A study of Mus musculus with 36 samples.

How the data were processed

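ChIP-seq with antibodies to CTCF and MBD3, and input chromatin, covered 36 samples of mouse embryonic stem cells in 12 groups of 3, with groups and replicate numbers taken from the labels. The labels' protocols describe sonicated, immunoprecipitated chromatin made into paired-end libraries, with PCR amplification, so fragments are not counted as independent molecules by identifiers. Per the submitters' processing notes, FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2 and bedtools 2.25.0 were used and the genome build was mm10. The authors deposited a peak list for each antibody and day, 8 in all, whose names show that replicates 1 to 3 were pooled before calling, and no such list was used here for input. In each list the authors give the fold enrichment at the summit (a ratio of fragments to the expected background). The authors also give the -log10 p and -log10 q of each peak, whose lowest -log10 q is 1.30 to 1.31 over the lists, a q near 0.05. The interval, the summit offset and these values are the peak caller's own, and fold enrichment was used to describe, rank or filter peaks within a list. Where folds of a site are given for several days, they depend on the background of each list and were not tested as a change.

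Rows with the same interval and several summits were counted as 1 peak with its summit of highest -log10 q, and chromosomes 1 to 19, X and Y were kept. Peaks were shared when they overlapped by 1 bp or more. Chance overlap was taken from 200 circular shifts of a list along each chromosome. Shares have exact (Clopper-Pearson) 95% intervals, differences of shares have intervals from 200 resamples of peaks, and medians within a list were set beside 10000 random sets of peaks. Within-deciles differences weight each decile of fold by the number of peaks with and without the other antibody. Because MACS2 reports fold and p by fixed formulas, the whole number of fragments over each summit and the expected background were recovered from them. A match within 0.1% of the -log10 p was found for 100% of the summits with a -log10 p under 30 in each list. Over all peaks a match was found for 98.1% (CTCF, day 0) to 99.9% (MBD3, day 0) of a list. On 1852 simulated summits with a -log10 p under 30 the right number was found for 100%. When fold and p were mixed up, 10.6% found any match. Stronger summits were not simulated. The lowest background shared by at least 0.5% of a list's peaks is its genome-wide level and follows the number and length of fragments of the immunoprecipitated libraries, and it is the only measure of depth used here.

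Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes on these chromosomes. It gives each gene's outer ends without strand or exons, so a window of 1 kb around either end replaced the planned window around transcription starts, and exons and introns were not told apart. A gene was occupied when a peak overlapped either window, and whether the peak itself was found on the other day was checked after the data were seen. The number occupied in each list was set beside 10000 random sets of protein-coding genes of the same size. The CTCF motif and CpG content of summits were not analysed here.

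The comparisons, gene lists and main alternatives were fixed before the data were examined. Genes of the lists are named when occupied on day 0 and not day 6 or the reverse, up to 4 per list, antibody and direction in order of the -log10 q of the peak, and when occupied by both proteins on all 4 days. A gene that meets this rule is not reported here. Values of Sox2, Pou5f1 and Rbbp7 beyond this rule, and the pseudogenes in the account of gene ends, were chosen after their values were seen. Outside the lists the 3 sites of highest fold per class are named, by day 0 fold for sites present on day 0 and by day 6 fold otherwise. MBD3 peaks in CTCF peaks are named for each day by their MBD3 fold of that day. Alternatives were a -log10 q of 10 or more, equal numbers of peaks per day, summits within 100 bp, overlap of 50% of the shorter peak, all chromosomes, separate summits, and windows of 5 kb. Added after seeing the data were leaving out peaks with a background over 10 times the list's level, leaving out peaks on pseudogenes, and counting peaks anywhere in a gene. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on 8000 simulated peaks against bedtools 2.31.1, and both counted 4781 overlaps. In 18 of 20 trials with 2 unrelated lists, the overlap fell inside the range of 20 shifts.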

Results

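Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in mouse embryonic stem cells with an antibody to CTCF, the zinc finger protein that binds insulators and the borders of chromatin loops, and with an antibody to MBD3, a subunit of the nucleosome remodelling and deacetylase complex NuRD. The 36 samples fall into 12 groups of 3, namely CTCF, MBD3 and input chromatin on days 0, 2, 4 and 6. The labels give the day of each sample and do not say what was done to the cells between day 0 and day 6. The cells were grown with leukaemia inhibitory factor on mouse fibroblast feeders. The series title places the question at the relation between NuRD and CTCF sites. The authors called peaks once per antibody and day on the 3 replicates together, which gives 8 peak lists and no spread between replicates. Below, a protein at a place means a peak of its antibody there. Carry-over between libraries could not be told apart from binding of both proteins, and cross-reaction was not tested. Differences between days are therefore given as values without a p-value. The 95% intervals of shares below are exact binomial intervals, those of differences come from resampled peaks, and both cover counting error only.

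CTCF had 47414 peaks on day 0, 28137 on day 2, 36787 on day 4 and 38109 on day 6, on chromosomes 1 to 19, X and Y. MBD3 had 10464 peaks on day 0, 1991 on day 2, 9006 on day 4 and 10875 on day 6, so both proteins had their shortest list on day 2. The strongest CTCF peak of day 0 by the authors' fold enrichment lay on chromosome 14 at 67211685 to 67212131 (mm10), between genes, 21385 bp from the nearer end of Ebf2, a transcription factor gene, and it was present on all 4 days. Its fold enrichment was 60.6, against a median of 6.67 over the list. The strongest MBD3 peak of day 0 lay at the same place, at 67211742 to 67212047, with a fold of 32.3 against a median of 4.07. Peaks were narrow, with median widths of 255 to 315 bp for CTCF and 213 to 228 bp for MBD3. The genome-wide background level of the peak caller, which follows the number and length of the fragments sequenced, was 2.87, 2.67, 1.83 and 1.87 fragments for CTCF on days 0, 2, 4 and 6. It was 1.51, 2.18, 1.93 and 1.41 for MBD3, so day 2 did not have the lowest level for either antibody. The order of the days within each antibody was the same at a -log10 q of 10 or more for CTCF, with 35513, 22159, 30301 and 31806 peaks. For MBD3 that limit left 3759, 1100, 3921 and 5694 peaks, and day 4 then exceeded day 0.

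**Figure D1:**
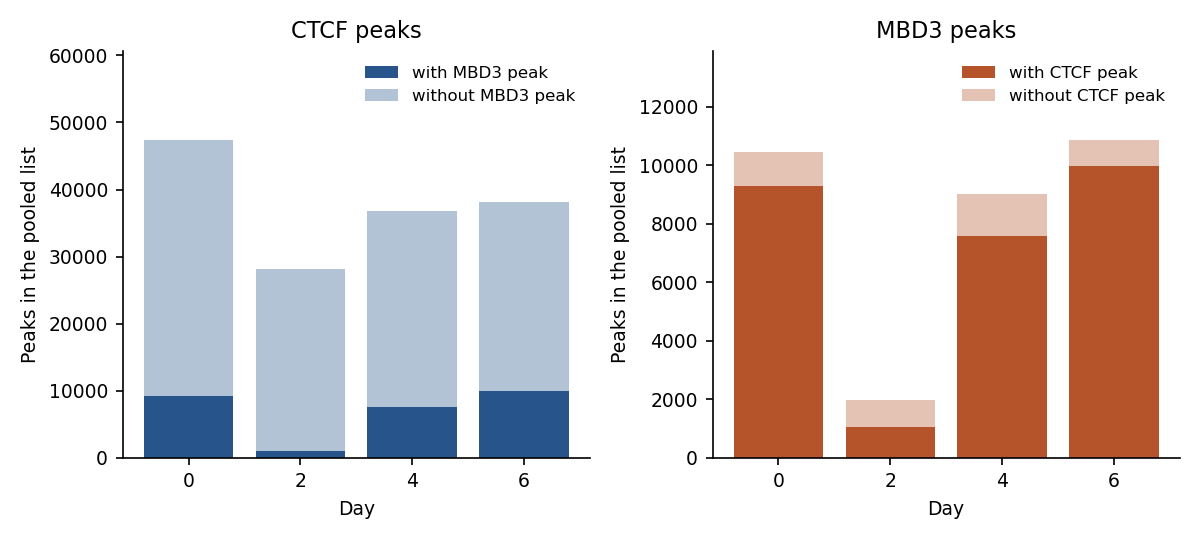
Number of CTCF peaks (left) and MBD3 peaks (right) in the pooled list of each day, as stacked bars; the dark part is peaks that overlap a peak of the other antibody on the same day. Each bar is a single pooled list without replicate error, and day 2 has the shortest bar for both antibodies, with 28137 CTCF and 1991 MBD3 peaks.

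Most strong CTCF sites were found on every day. Of 53682 merged CTCF sites, 25409 (47.3%) had a peak on all 4 days, 11076 were found on day 0 only and 361 were absent on day 0 and present on days 2, 4 and 6. After the site near Ebf2, the highest folds among the sites of all 4 days were 50.7 at 97783999 to 97784669 on chromosome 15, at the end of the haem transporter gene Slc48a1, and 48.3 at 45944597 to 45945208 on chromosome 11, at the end of Lsm11, whose product takes part in histone mRNA processing. Among the sites of day 0 only, the highest folds were 17.0 on chromosome 13 at 94843049 to 94843584, 393 bp from an end of the tubulin folding gene Tbca, 13.9 inside Cracdl on chromosome 1 at 37675428 to 37675824 and 13.4 inside Vwa8 on chromosome 14 at 79134848 to 79135157. The sites that appeared after day 0 were led on day 6 by a peak of fold 19.4 on chromosome 4 at 143238608 to 143239146, 26107 bp from Prdm2, a histone methyltransferase gene. The next 2 lay inside Rabgap1l, on chromosome 1 at 160377686 to 160377961 with a fold of 18.1, and inside Sel1l3, on chromosome 5 at 53123547 to 53123851 with a fold of 16.6. Of the day 0 CTCF peaks, 56.0% (95% interval 55.6 to 56.4) overlapped a day 2 peak, 70.5% (70.0 to 70.9) a day 4 peak and 72.1% (71.7 to 72.5) a day 6 peak, where 200 circular shifts of the later list gave at most 1.18%. In the other direction 94.8%, 91.2% and 90.0% of the peaks of days 2, 4 and 6 lay on a day 0 peak. The share followed the fold enrichment: among the decile of day 0 peaks with the highest fold 99.1%, 99.9% and 99.9% were found on days 2, 4 and 6, and among the lowest decile 1.75%, 6.77% and 7.19%. With the same number of peaks taken from each list, 2006 sites were found on day 0 only. The day 0 list was the longest and had the highest background level of the CTCF lists. The part of depth in its sites of day 0 only was not tested.

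MBD3 sites overlapped less between days than CTCF sites did. Of 18378 merged MBD3 sites, 901 (4.90%) had a peak on all 4 days, 3687 were found on day 0 only and 243 were absent on day 0 and present on days 2, 4 and 6. The sites of all 4 days were led by the one near Ebf2, by 3447453 to 3447761 on chromosome 6, 9483 bp from Hepacam2, with a fold of 31.4, and by 29619478 to 29619787 on chromosome 2, at the end of the guanine nucleotide exchange factor gene Rapgef1, with a fold of 29.8. All 3 carried a CTCF peak on every day. The strongest MBD3 sites of day 0 only were inside Mansc4 on chromosome 6 at 147076167 to 147076745 (fold 14.5), 133620 bp from Spin1 on chromosome 13 at 50964201 to 50964428 (fold 11.3) and 16821 bp from Adam30 on chromosome 3 at 98180841 to 98181141 (fold 10.7). CTCF had a peak at these 3 places on all 4 days. The strongest MBD3 sites that were absent on day 0 carried no CTCF peak on any day. They were the pseudogene Gm6863 on chromosome 12 at 96922410 to 96923056 with a fold of 102.8 on day 6, the pseudogene Gm6368 on chromosome X at 141980076 to 141980924 with a fold of 96.3, and a stretch inside the chaperone gene Hsp90ab1 on chromosome 17 at 45568881 to 45569139 with a fold of 64.6. Of the day 0 MBD3 peaks 10.2% (9.60 to 10.8) overlapped a day 2 peak, 48.2% (47.3 to 49.2) a day 4 peak and 54.0% (53.0 to 54.9) a day 6 peak, and shifted lists gave at most 0.334%. The day 2 share is limited by the short day 2 list. With equal numbers of peaks per day the shares were 37.5%, 57.6% and 54.0% on days 2, 4 and 6, so day 2 stayed lowest. Without peaks of high control background the day 2 share was 5.87%. Even in the decile with the highest day 0 fold, 46.3% of the MBD3 peaks were found on day 2, against 73.8% on day 4 and 83.9% on day 6. With the same number of peaks taken from each list, 611 MBD3 sites were found on day 0 only and 597 on all 4 days.

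MBD3 peaks lay mostly inside CTCF peaks of the same day. The share was 88.9% on day 0 (9298 of 10464, 95% interval 88.2 to 89.5), 53.7% on day 2 (1069 of 1991, 51.5 to 55.9), 84.3% on day 4 (7590 of 9006, 83.5 to 85.0) and 91.8% on day 6 (9988 of 10875, 91.3 to 92.4), and shifted CTCF lists gave at most 1.42%. Conversely, 19.5%, 3.80%, 20.6% and 26.1% of the CTCF peaks of days 0, 2, 4 and 6 had an MBD3 peak. These shares depend on the lengths of the lists. With equal numbers of peaks per day they were 6.55%, 3.80%, 5.99% and 5.97%, lowest on day 2 again. In that setting 1991 MBD3 peaks can reach only a small part of 28137 CTCF peaks, so the values restate the MBD3 shares. The summits of both proteins were close, with a median distance from an MBD3 summit to the nearest CTCF summit of 14, 92, 14 and 10 bp on those days. Among co-occupied sites the highest MBD3 folds on day 0 were those near Ebf2, near Hepacam2 and at Rapgef1, where the CTCF folds were 60.6, 42.9 and 42.9. On days 2, 4 and 6 a site inside Ctif, a translation initiation gene, on chromosome 18 at 75599760 to 75600235 on day 2, had MBD3 folds of 20.1, 25.8 and 37.7. Day 2 was further led by a site inside the vesicle trafficking gene Sec22c (chromosome 9, 121697531 to 121698033, MBD3 fold 16.5) and by a site 140053 bp from Lmcd1 (chromosome 6, 112133589 to 112133822, fold 14.8). On day 4 the strongest sites besides Ctif were inside Apbb2 (chromosome 5, 66326413 to 66326812, fold 29.5) and inside Nxpe3 (chromosome 16, 55863445 to 55863779, fold 26.6). On day 6 they were the pseudogene Gm8806 (chromosome X, 80534009 to 80534420, fold 37.5), where CTCF had a fold of 3.83 and a peak on day 6 alone, and the noncoding gene Gm16230 (chromosome 10, 127674665 to 127675134, fold 37.2). Without peaks on annotated pseudogenes the share of MBD3 peaks inside CTCF peaks on day 2 was 64.6%.

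CTCF peaks that carried MBD3 had higher CTCF fold enrichment than the rest of their list. The median CTCF folds with and without MBD3 were 12.7 and 5.75 on day 0, 9.04 and 5.42 on day 2, 13.3 and 7.52 on day 4, and 14.4 and 7.31 on day 6. Each median with MBD3 exceeded the medians of all 10000 random sets of the same size from its list, whose highest values were 6.87, 5.77, 8.82 and 9.17. In the top decile of CTCF fold 71.5% of the day 0 peaks and 81.2% of the day 6 peaks had an MBD3 peak, against 6.45% and 1.36% in the lowest decile. Stag2, a cohesin subunit gene on chromosome X, was an example on day 0, with a CTCF fold of 43.1 and an MBD3 fold of 15.0. Within the MBD3 lists the relation was weaker and changed direction: median MBD3 folds with and without CTCF were 4.17 and 3.17 on day 0, 4.05 and 4.70 on day 2, 3.92 and 3.30 on day 4, and 4.56 and 4.92 on day 6. The order on days 2 and 6 turned when peaks on pseudogenes were left out, and the order on day 4 turned at a -log10 q of 10 or more.

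**Figure D2:**
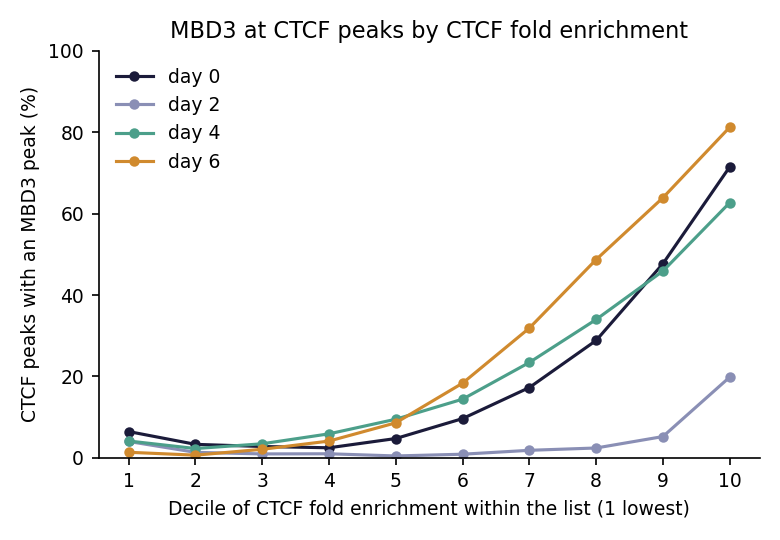
Share of CTCF peaks that overlap an MBD3 peak of the same day (percent, vertical axis) in deciles of the authors' CTCF fold enrichment within each list (horizontal axis, 1 lowest), with a line per day. The share in the top decile was 71.5% on day 0 and 81.2% on day 6, and the day 2 line lies under the others from decile 3 upward.

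MBD3 peaks of day 0 that lay in a CTCF peak were found on day 6 more often than MBD3 peaks outside CTCF. The shares were 58.5% (5436 of 9298, 95% interval 57.5 to 59.5) and 18.3% (213 of 1166, 16.1 to 20.6), and within deciles of the day 0 MBD3 fold the difference was 31.7 percentage points (29.3 to 34.0, from resampled peaks). In decile 1, which held 332 of the peaks outside CTCF, the order was reversed, with 34.8% kept with CTCF and 38.0% without. In every other decile the share was higher with CTCF. Sites at Stag2, at Ctcf itself and at the collagen gene Col1a1 had a peak of both antibodies on every day. With equal numbers of peaks per day, the difference within deciles turned to -8.22 points. That setting kept the 1991 MBD3 and the 28137 CTCF peaks of highest -log10 q on each day, so weaker peaks of both antibodies no longer counted. Of these day 0 MBD3 peaks 92.6% lay in a CTCF peak, which leaves fewer outside, and no interval was computed. The cause of the turn was not tested. CTCF peaks with MBD3 on day 0 were kept in 93.2% (92.7 to 93.7) of cases and CTCF peaks without it in 67.0% (66.6 to 67.5). That difference was not detectable within deciles of the CTCF fold, at 0.16 points (-0.42 to 0.67), and it went both ways: 14.0% of the peaks with MBD3 and 26.7% of those without were kept in decile 2, 38.6% and 49.9% in decile 3, and 96.5% and 91.5% in decile 6. Leaving out peaks with a control background over 10 times the level of the list gave -6.03 points.

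**Figure D3:**
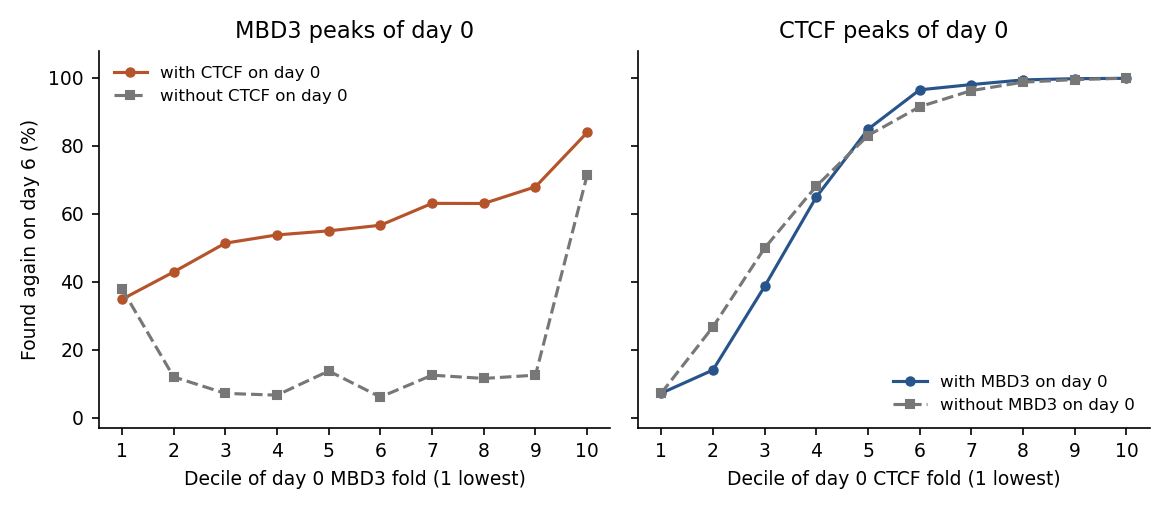
Share of day 0 peaks that overlap a day 6 peak of the same antibody (percent, vertical axis) in deciles of the day 0 fold enrichment (horizontal axis, 1 lowest), for MBD3 (left) and CTCF (right); solid lines are peaks with and dashed lines peaks without the other antibody on day 0. The MBD3 lines lie apart in deciles 2 to 9, the last point of the dashed MBD3 line rests on 7 peaks, and the CTCF line with MBD3 lies under the other in deciles 2 to 4.

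Peaks were more frequent near gene ends than the share of the genome there. Summits within 1 kb of either annotated end of a protein-coding gene made up 15.4%, 10.8%, 10.9% and 10.8% of CTCF peaks and 18.5%, 19.6%, 21.0% and 13.8% of MBD3 peaks on days 0, 2, 4 and 6, where such windows cover 2.91% of the genome. CTCF peaks of day 0 only were near gene ends in 28.4% of cases (3146 of 11076), day 0 peaks shared with another day in 11.5%, and day 6 peaks of that day only in 4.27%. Much of this came from weak peaks. In the lowest decile of day 0 CTCF fold the shares were 46.8% for peaks of day 0 only and 27.7% for shared peaks, and in deciles 4 to 6 they were 8.83% and 9.81%. MBD3 peaks of a single day were near gene ends in 16.6%, 13.3%, 22.9% and 6.85% of cases on days 0, 2, 4 and 6, and peaks at sites of all 4 days in 22.0%, 22.2%, 22.1% and 22.1%. Pseudogenes were overlapped by 2.28%, 20.3%, 4.10% and 4.03% of MBD3 peaks on days 0, 2, 4 and 6, and by 1.04% to 1.16% of CTCF peaks. Among MBD3 peaks of fold 15 or more, pseudogenes lay under 0 of 87 on day 0, 64 of 88 on day 2, 45 of 128 on day 4 and 75 of 242 on day 6. The ribosomal protein pseudogenes Rplp2-ps1 and Rpl14-ps1 on day 2 had MBD3 folds of 88.0 and 56.8.

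CTCF lay within 1 kb of an end of 7518 of 21887 protein-coding genes on day 0 and of 3408, 4448 and 4604 on days 2, 4 and 6. MBD3 did so at 2194, 466, 2157 and 1743 genes. Between day 0 and day 6, CTCF was present on both days at 4463 genes, on day 0 alone at 3055 and on day 6 alone at 141, and for MBD3 these numbers were 1216, 978 and 527. A peak at the edge of a window can leave it by being narrower: at 70 of the 3055 and 22 of the 141 genes a CTCF peak at the gene overlapped a peak of the other day that lay outside the window, and for MBD3 at 11 of 978 and 10 of 527. With equal numbers of peaks per day, CTCF was near 4282 genes on day 0 and 3659 on day 6, and MBD3 near 562, 466, 642 and 441 on days 0, 2, 4 and 6. The CTCF background level was 2.87 on day 0 and 1.87 on day 6. How much of the day 0 excess of CTCF genes comes from depth was not tested. Among the 252 genes of the 13 lists, 52 had CTCF on day 0 and not on day 6, and 45 of those 52 rested on a day 0 peak below the 30th percentile of fold in its list. Only Meg3, Eef1a1 and Pcdhb18 had CTCF on day 6 and not on day 0. For Sox17, Peg3, Hoxa9 and Meg3 the CTCF peak itself was found on both days, and for Tubb5 the MBD3 peak.

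Of the 22 core and naive pluripotency genes, CTCF was at the ends of 6, 1, 2 and 2 on days 0, 2, 4 and 6, and 33.1%, 12.0%, 14.4% and 13.0% of random gene sets of that size had as few or fewer. Within 5 kb of an end CTCF was at 17, 11, 11 and 12 of them, and with equal numbers of peaks per day at 2, 1, 2 and 1 within 1 kb, where MBD3 was at 1, 2, 1 and 0. Tfcp2l1 (fold 3.39), Utf1 (2.77), Nr0b1 (3.68) and Klf2 (1.65) had CTCF on day 0 alone. MBD3 was at 2, 2, 3 and 1 of these genes, and none of those MBD3 peaks overlapped a CTCF peak. Sox2, a core factor of the stem cell state and a gene without introns, had an MBD3 peak on every day, with folds of 2.65, 7.50, 6.02 and 3.08. Pou5f1, which encodes Oct4, had an MBD3 peak on days 2 and 4 (4.48 and 4.39), and Dppa5a on day 0 alone (2.13). Of the 10 formative and primed pluripotency genes, 5 had CTCF on day 0 and 0 on each later day, and with equal numbers of peaks per day 0 had it on any day. The day 0 genes included Sall2 (fold 7.78), Pou3f1 (2.79), Lef1 (2.99) and Dnmt3b (2.27). MBD3 was at Zic2 (3.88) and Zic5 (3.49), neighbouring zinc finger genes, on day 0 and at 0 genes of this list later, and with equal numbers of peaks per day at 0 genes on every day.

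At lineage genes most CTCF peaks found on day 0 and not on day 6 were weak. With equal numbers of peaks per day CTCF was at 2 neuroectoderm genes on each day, at 4, 3, 5 and 4 mesoderm and endoderm genes and at 1, 0, 1 and 1 trophoblast genes on days 0, 2, 4 and 6, and MBD3 was at 0 genes of these lists except 1 trophoblast gene on day 6. With all peaks CTCF was at 7, 2, 3 and 2 of 16 neuroectoderm genes, and Olig2 (fold 3.59), Zic1 (3.58), Neurog1 (2.63) and Hes5 (2.72) had it on day 0 and not on day 6. MBD3 was at 1, 0, 1 and 2 of them, with a peak of fold 4.12 at the neuronal tubulin gene Tubb3 on day 6 alone. Of 18 mesoderm and endoderm genes CTCF was at 8, 3, 6 and 4 and MBD3 at 3, 0, 4 and 1. The endoderm factor gene Sox17 had a strong CTCF peak on day 0 (fold 18.6, above 96.7% of the list; chromosome 1, 4491725 to 4492543) at the edge of its window. The peak was found on all 4 days, with folds of 3.77, 6.59 and 6.33 on days 2, 4 and 6, and reached the window on days 0 and 4. Lhx1 (3.81), Kdr (3.27) and Msx1 (2.33) also had CTCF on day 0 and not day 6. MBD3 was at Mesp1, Eomes and Sox17 on days 0 and 4 with day 0 folds of 3.92, 3.84 and 3.53, and at Gata6 on days 4 and 6, with a day 6 fold of 2.55. Of 8 trophoblast genes CTCF was at 4, 0, 1 and 1 and MBD3 at 1, 0, 1 and 1. Ascl2 (3.53), Cdx2 (3.42) and Tfap2c (2.06) had CTCF on day 0 only.

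The CTCF and cohesin list, which also holds Yy1 and Zfp143, carried MBD3 more often than most random gene sets, as did the housekeeping list. On day 0 MBD3 was at 7 of the 13 genes of the CTCF and cohesin list, above the highest of 10000 random sets (6). It was at 3 on each later day, above 99.8%, 87.6% and 92.2% of the random sets on days 2, 4 and 6. CTCF was at 7, 5, 5 and 5, above 88.07%, 96.13%, 89.35% and 88.02% of random sets. At 6 of the 7 day 0 genes MBD3 lay in a CTCF peak, and the random sets were not matched for CTCF. With equal numbers of peaks per day MBD3 was at 3 of the 13 genes on each day, so the difference between day 0 and the later days did not hold. Such comparisons were made for 104 counts without adjustment. Ctcf (chromosome 8, 105636593 to 105636999) and Stag2 (chromosome X, 42149066 to 42149349) had both proteins on all 4 days, with day 0 MBD3 folds of 8.07 and 15.0. Yy1 (3.27), the cohesin genes Smc3 (3.95) and Pds5a (2.94), and Zfp143 (2.97) had MBD3 on day 0 and not day 6, and Yy1 (2.95) and Zfp143 (2.02) also had CTCF on day 0 and not day 6. Of 14 NuRD genes CTCF was at 8, 2, 2 and 3, and Gatad2a (2.83), Rbbp4 (2.58), Mbd2 (2.86) and Mta1 (1.86) had it on day 0 only. MBD3 was at 2, 3, 4 and 1 NuRD genes, above 58.8%, 99.7%, 96.0% and 31.3% of random sets, and 1, 0, 0 and 0 of these genes had MBD3 in a CTCF peak. Hdac1 had MBD3 on day 0 alone (2.69) and Rbbp7, a histone chaperone gene, on every day with folds of 4.51, 14.4, 8.30 and 6.92. Of 9 DNA methylation genes CTCF was at 6, 1, 1 and 1 and MBD3 at 0, 0, 2 and 0. With equal numbers of peaks per day CTCF was at 3, 2, 2 and 2 NuRD genes and at 1, 1, 0 and 0 DNA methylation genes, and MBD3 at 1, 3, 1 and 1 NuRD genes and at 0 DNA methylation genes. Tdg (2.51), Dnmt3b (2.27), Tet1 (2.76) and Tet2 (2.38) had CTCF on day 0 only.

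Of 22 imprinted genes CTCF was at 8, 1, 5 and 4 and MBD3 at 1, 0, 0 and 2. Mest (6.79), Peg3 (4.08), Grb10 (4.33) and Inpp5f (2.48) had CTCF on day 0 and not day 6, though the Peg3 peak was found on day 6 outside the window. Meg3, a maternally expressed noncoding RNA gene, had CTCF in its window on days 4 and 6, with a day 6 fold of 11.6 on chromosome 12 at 109541981 to 109542353, and the peak was present on days 0 and 2 (7.15 and 8.18) outside the window, and Gnas had MBD3 on day 6 (3.22). Of 15 housekeeping genes CTCF was at 5, 1, 2 and 3 and MBD3 at 4, 2, 4 and 4, above 94.0%, 96.2%, 94.7% and 97.0% of random sets. Ppia (3.26) and Pgk1 (2.31) had CTCF on day 0 and not day 6, and the elongation factor gene Eef1a1 had it on day 6 (3.93). Polr2a had MBD3 on day 6 alone (4.45), and Tubb5 in its window on day 0 alone (1.84), where the peak was found on all 4 days. Of the 10 markers of fibroblasts, the feeder cell type, CTCF was at 5, 3, 3 and 3 and MBD3 at 3, 1, 1 and 3. Col1a1 had both proteins on all 4 days (chromosome 11, 94936846 to 94937295, day 0 MBD3 fold 7.92 and CTCF fold 18.8), and Twist2 (3.10) and Twist1 (2.03) had CTCF on day 0 only. With equal numbers of peaks per day CTCF was at 5, 1, 3 and 3 imprinted genes, at 1, 1, 2 and 2 housekeeping genes and at 3 fibroblast markers on each day, while MBD3 was at 0 imprinted genes, at 1, 2, 2 and 2 housekeeping genes and at 1 fibroblast marker on each day. A peak at these genes does not measure their expression.

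The clustered protocadherins were the list with the highest share of genes with CTCF. CTCF was at 55, 42, 49 and 51 of the 58 clustered protocadherin genes, which encode neuronal adhesion proteins on chromosome 18, above the highest of 10000 random gene sets on each day (35, 21, 24 and 25). The Pcdhg genes share an annotated end near 37841870, where a single CTCF peak on each day (fold 6.73, 6.23, 12.1 and 10.8) counts for each of the 22 genes, which the random sets do not allow for. The distinct CTCF peaks at the ends of the list numbered 64, 44, 56 and 56. Pcdha4 (7.60), Pcdha2 (5.51), Pcdha11 (4.81) and Pcdhb22 (2.54) had CTCF on day 0 and not day 6, and Pcdhb18 on day 6 alone (10.3). MBD3 was at 11, 0, 27 and 25 genes, and at 1, 0, 0 and 0 with equal numbers of peaks per day. At the shared end a single MBD3 peak of day 4 (fold 3.36) and of day 6 (37841349 to 37841651, fold 4.16) likewise counts for each Pcdhg gene, and the distinct MBD3 peaks at the ends of the list numbered 12, 0, 8 and 12. Counted as separate peaks in the Pcdha, Pcdhb and Pcdhg clusters, MBD3 had 6, 6 and 4 on day 0, 0, 1 and 0 on day 2, 4, 3 and 3 on day 4, and 1, 2 and 9 on day 6. Pcdhac1 (4.85), Pcdhb8 (7.58), Pcdha8 (4.60) and Pcdha6 (4.59) had MBD3 on day 0 and not day 6, and Pcdhgb7 (5.19), Pcdhgb6 (5.79), Pcdhb17 (5.73) and Pcdhga1 (4.16) the reverse. Of 39 Hox genes, which pattern the body axis, CTCF was at 14, 8, 9 and 9 and MBD3 at 7, 0, 6 and 6, and with equal numbers of peaks per day at 10, 8, 9 and 9 and at 1, 0, 1 and 1. A CTCF peak of fold 12.9 on day 0 (chromosome 6, 52221432 to 52222309) reached the window of Hoxa9 on day 0 alone and was found on all 4 days, with a fold of 20.3 on day 6. Hoxd9 (3.99), Hoxb7 (4.15) and Hoxb9 (3.03) had CTCF on day 0 and not day 6. MBD3 was at Hoxc5 (6.45), Hoxb5 (4.64) and Hoxa10 (3.88) on day 0 and not day 6, and at Hoxb6 (3.18) and Hoxa4 (2.39) on day 6 alone.

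**Figure D4:**
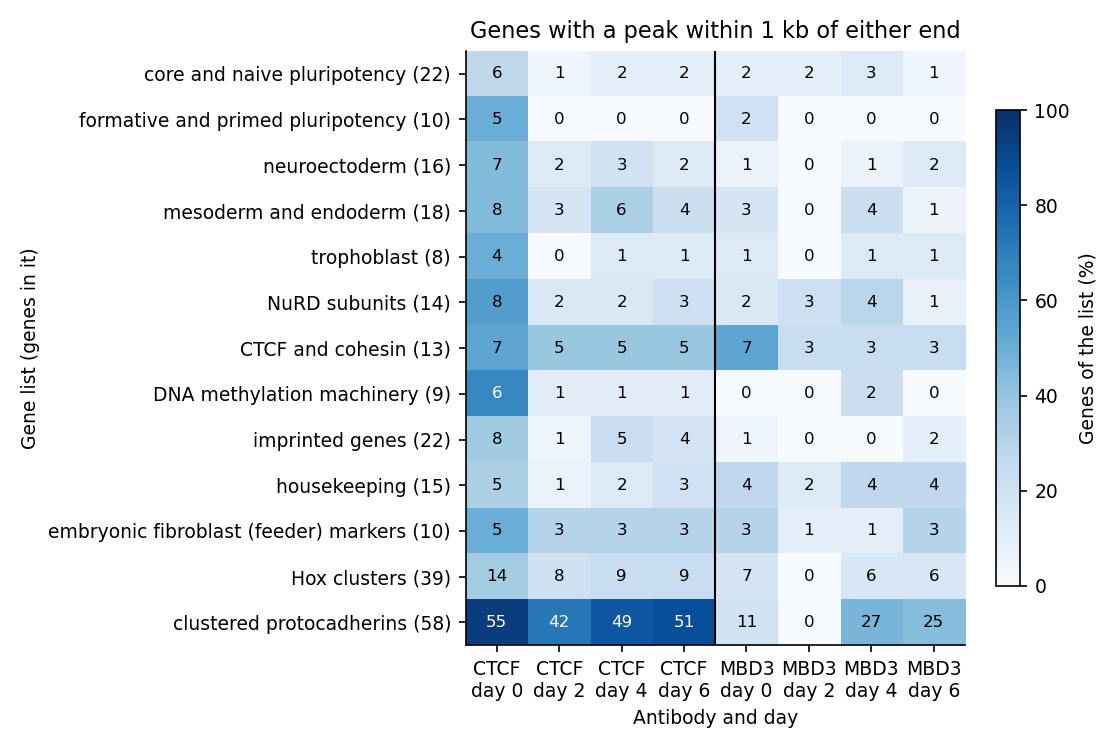
Genes of each fixed list (rows, list size in brackets) with a peak within 1 kb of either annotated end, by antibody and day (columns); the number is the count of genes and the shade is its percent of the list. Clustered protocadherins have the darkest CTCF cells, with 55, 42, 49 and 51 of 58 genes.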

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

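The tests in this part were chosen after the results were seen. Peak summits on mitochondrial DNA and unplaced scaffolds, counted before summits of the same interval were joined, lie outside the chromosomes compared and stand above the 3 that a count of 0 allows. The CTCF lists held 51, 80, 63 and 39 such summits on days 0, 2, 4 and 6, of which 7, 32, 24 and 3 were on mitochondrial DNA. The MBD3 lists held 41, 60, 47 and 71, of which 26, 31, 28 and 24 were on mitochondrial DNA.

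Both antibodies had their shortest list on day 2, with 28137 CTCF and 1991 MBD3 peaks. Fewer sequenced fragments of the same length would give day 2 the lowest background level, but it was 1.46 times the lowest of the other days for CTCF and 1.55 times for MBD3. That argues against lower depth of the immunoprecipitated libraries only if fragment length was alike between days, which was not examined. It does not cover the depth of the input libraries. A lower yield of the immunoprecipitations on day 2 would lower the excess of fragments at day 0 peaks found on all 4 days. Peaks of high day 0 background or on pseudogenes were left out. Divided by each list's background level, this excess on day 2 was 0.573 times that of the lowest other day for CTCF (24717 sites). For MBD3 it was 0.498 times (574 sites). Both go with a lower yield, though a higher background level also lowers the divided value. Undivided median fragments at the summits were 96, 56, 70 and 81 for CTCF on days 0, 2, 4 and 6, and 73, 59, 90 and 82 for MBD3. A change in the cells on day 2 that lowers binding at these sites would look alike, and the pooled lists do not show whether all 3 replicates share it. No test here separates yield from such a change.

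MBD3 peaks lay inside CTCF peaks, in 88.9%, 84.3% and 91.8% of cases on days 0, 4 and 6. Places with high control signal do not account for it, since on average 10.6% of these MBD3 peaks had a background over 10 times the level of the list. Carry-over of CTCF libraries into the MBD3 libraries of the same day would give a nearly fixed ratio of fragments, and the spread of that ratio beyond counting error, at those of the 1000 strongest CTCF sites that had an MBD3 peak (84.3%, 78.7% and 90.9% on days 0, 4 and 6), was 12.6% at its lowest (day 6) and 20.9% at its highest. Ratios between CTCF lists of different days spread by 8.08% to 24.4%, so carry-over cannot be told apart from binding of both proteins, because the ranges overlap, replicates are pooled and leaving out sites without an MBD3 peak can narrow the spread. Binding of MBD3 at CTCF sites stays open as well, and cross-reaction of the antibody was not tested.

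MBD3 peaks of fold 15 or more lay on pseudogenes 184 times on days 2, 4 and 6, and 0 of 87 times on day 0. Extra copies of these sequences would raise CTCF libraries too, yet 1.09% of them (2 of 184) had a CTCF peak of the same day. A candidate explanation is sequence of mature transcripts in the MBD3 libraries, which aligns to intronless copies of abundant genes. Of the named pseudogenes under these peaks at least 72.2% on each day carried a ribosomal protein name, against 13.9% of all named pseudogenes in the annotation. These shares rest on 17, 13 and 18 names on days 2, 4 and 6, because most pseudogenes under these peaks carry Gm numbers, which were left out. Many places recur from day to day, among them Rplp2-ps1, Rpl14-ps1 and Rps23-ps1, so the days are not separate support. The 184 peaks count such places once per day, and Rpl7a-ps12 and Rps7-ps3 lie under the same peak. Under MBD3 peaks of any fold outside CTCF, ribosomal protein names were 29 of 58 on day 0. They were 59 of 113, 50 of 91 and 58 of 112 on days 2, 4 and 6, so the excess of such names is also seen under the weaker peaks of day 0. Binding of MBD3 at these places after day 0 was not tested and stays open.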

How the results depend on the processing

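All alternatives named here were planned except 3 chosen after seeing the data: leaving out high-background peaks, leaving out peaks on pseudogenes, and counting peaks anywhere in a gene. No paired analysis was possible because the 3 replicates of each group are pooled in a single list and no result comes from a test, and for the same reason leaving out each replicate was not run. The motif alternatives were not run. What depth limits was not tested, as no list was thinned to a common depth, and where no reason is given the cause was not tested. A -log10 q of 10 or more, which by construction removes weak peaks, left 3759, 1100, 3921 and 5694 MBD3 peaks on days 0, 2, 4 and 6. All chromosomes, separate summits and both filters kept each peak count within 1.5 times.

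Day 0 peaks found on day 6 were 72.1% for CTCF and 54.0% for MBD3. These became 81.7% and 65.3% at the stricter q, 71.6% and 52.5% by summits, and 69.4% and 44.4% without high-background peaks, and CTCF reached 86.5% with equal numbers. CTCF sites on day 0 only fell from 11076 to 5113 at the stricter q and 2006 with equal numbers, and MBD3 ones from 3687 to 923 and 611. MBD3 sites on all 4 days went from 901 to 574, 597 and, without high-background peaks, 446, while those of CTCF (25409) stayed within 1.5 times.

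The share of MBD3 peaks with CTCF on days 0, 2 and 4 was 94.0%, 50.5% and 89.1% at the stricter q. By summits it was 84.0%, 50.1%, 82.1% and 90.5% on the 4 days, and without peaks on pseudogenes 90.0%, 64.6%, 86.9% and 94.8%. With equal numbers it was 92.6% on day 0 and 84.4% on day 6, and without high-background peaks 89.9% on day 0 and 51.2% on day 2.

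MBD3 kept on day 6, with minus without CTCF, was 40.2 points and 31.7 within deciles of fold. It was 9.46 and 14.5 at the stricter q, 45.1 and 36.9 by summits, 45.7 and 36.5 without high-background peaks, 48.1 and 39.1 without pseudogenes, and turned to -8.04 and -8.22 with equal numbers. Equal numbers also shortened the CTCF list of day 0 and the MBD3 lists of days 0 and 6. Fewer MBD3 peaks then lay outside CTCF, and the cause of the turn was not tested. CTCF kept with minus without MBD3 was 26.2 points, and 19.2 at the stricter q, 13.3 with equal numbers, 28.3 by summits and 18.98 without high-background peaks. Within deciles it was 0.16, and 1.22, 0.93 and, without high-background peaks, -6.03.

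The log2 ratio of median CTCF fold with over without MBD3 was 1.14, 0.74, 0.83 and 0.98 on days 0, 2, 4 and 6. It was 1.01, 0.84, 0.72 and 0.82 at the stricter q, 1.16 and 0.80 by summits on days 0 and 2, and 0.81, 0.85 and 0.96 without high-background peaks on days 2, 4 and 6. In the MBD3 lists the ratio with over without CTCF turned to 0.12 on day 2 and 0.22 on day 6 without pseudogenes, 0.0031 on day 6 by summits and -0.50 on day 4 at the stricter q.

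Windows of 5 kb, wider by construction, gave gene-end shares of 33.7% and 28.5% for CTCF and 38.6% and 33.6% for MBD3 on days 0 and 6. The stricter q gave 12.9% for CTCF on day 0 and 21.0% and 15.9% for MBD3. Genes with CTCF on days 0 and 6 numbered 12285 and 9720 with 5 kb and 12413 and 10340 with peaks anywhere in the gene, and 4282 on day 0 with equal numbers. For MBD3 these were 4410 and 4171, 4760 and 4592, and 562 and 441.

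Of 104 counts per gene list, antibody and day, 89 were higher with 5 kb, 53 were lower with equal numbers and 2 were lower without pseudogenes. Of the remaining values, 13 were higher and 9 lower at the stricter q, 4 and 14 by summits, 0 and 14 by 50% overlap, 6 and 9 with equal numbers, 0 and 18 without high-background peaks, 16 and 10 without pseudogenes, 8 and 0 with 5 kb, and 4 and 0 anywhere in the gene.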

Other observations

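The values in this part were chosen after the data were seen. At 4 genes picked by their values, strong MBD3 peaks lay on days 2, 4 and 6. Of the 15 housekeeping genes fixed beforehand, MBD3 was at the ends of 4, 2, 4 and 4 on days 0, 2, 4 and 6. Anywhere in the gene or within 1 kb of it, MBD3 was at 5, 4, 5 and 5. These counts are not measures of fold. The housekeeping gene Eef1a1 had MBD3 folds of 2.54, 11.7, 6.10 and 6.89. Rplp0 went the other way, with 9.87 on day 0, no peak on day 2, and 5.77 and 4.85 on days 4 and 6. Rpl4, a ribosomal protein gene on chromosome 9, had a highest MBD3 fold of 29.8, 15.6 and 31.0 on days 2, 4 and 6 and no MBD3 peak on day 0. Hsp90ab1 had highest folds of 50.6, 28.7 and 64.6 on days 2, 4 and 6 and none on day 0, and the nucleolin gene Ncl had 19.5, 18.6 and 24.3. The glycolysis gene Pkm had 20.6, 21.7 and 21.2, and at another place in the gene, 59659772 to 59659999, a peak of fold 4.40 on day 0. Outside CTCF peaks, pseudogenes lay under 12.8% of MBD3 peaks on day 0 and under 39.5%, 20.5% and 39.6% on days 2, 4 and 6.

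The Hoxa cluster on chromosome 6 (52155367 to 52260880) held 9, 5, 6 and 6 CTCF peaks and 4, 0, 4 and 4 MBD3 peaks on days 0, 2, 4 and 6. The Hoxb cluster on chromosome 11 (96194316 to 96368254) held 16, 8, 11 and 11 CTCF peaks and 6, 0, 3 and 4 MBD3 peaks. In the Hoxc cluster on chromosome 15 CTCF had 6, 3, 5 and 4 peaks and MBD3 had 2, 0, 2 and 1, and in the Hoxd cluster on chromosome 2 CTCF had 9, 4, 6 and 6 and MBD3 had 3, 0, 1 and 2.

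MBD3 peaks of one day were also set against the CTCF peaks of other days. Of the day 0 MBD3 peaks 88.9% lay in day 0 CTCF peaks and 80.3%, 82.6% and 82.8% in those of days 2, 4 and 6. Of the day 2 MBD3 peaks 53.7% lay in CTCF peaks of day 2 and 48.6%, 46.2% and 46.2% in those of days 0, 4 and 6. Of the day 4 MBD3 peaks 84.3% lay in CTCF peaks of day 4 and 87.6%, 82.5% and 83.9% in those of days 0, 2 and 6. Of the day 6 MBD3 peaks 91.8% lay in CTCF peaks of day 6 and 92.0%, 89.9% and 91.8% in those of days 0, 2 and 4. Chromosome X held 2.42%, 2.03%, 2.51% and 2.64% of the CTCF peaks and 1.52%, 3.37%, 1.67% and 1.75% of the MBD3 peaks on days 0, 2, 4 and 6.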
